A study of Mus musculus with 2 samples.

How the data were processed

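Peak lists from ATAC-seq of 2 biological replicates of mouse embryonic liver were analysed, with no reads or coverage tracks. Per the labels, DNA was tagmented with a Nextera kit and peaks refer to the mm10 assembly. The aligner, the peak caller and their settings are not given in the sources used here, and the depth of the libraries is unknown, so no interval rests on reads. Each deposited list gives a signal value per peak, whose scale is not stated, and the −log10 p-value that the authors' peak caller assigned. The 4 ranked lists deposited also carry a score, the −log10 of the global irreproducible discovery rate (IDR), which measures how well ranks repeat between replicates or pseudoreplicates. The list of a single replicate can only compare its pseudoreplicates, so its threshold does not measure agreement between the 2 replicates. The 8 columns per ranked list that hold values of single replicates or pseudoreplicates were not used here. Each replicate had an IDR-thresholded list, the main list here, a longer overlap-thresholded list of pseudoreplicated peaks and a ranked list, and further lists covered both replicates, of which the conservative IDR-thresholded list was used for signals of named genes and loci. Despite its name, the conservative list was longer than the thresholded list of either replicate, with 28135 regions against 22069 and 21503.

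Lists held several records per region, one per summit, in 59.5% and 66.3% of the regions of replicates 1 and 2. A peak was therefore a distinct region, represented by its strongest summit, a choice made after the lists were seen, with every record counted as the alternative. Regions were set against GRCm38 and GENCODE M21. For genomic shares, correlations and motifs, a promoter peak had its summit within 1000 bp of an annotated start of a protein-coding gene. The other peaks were distal. When genes were counted, a promoter peak was a region with any part within 1000 bp of a start of the gene. Distal peaks of genes had no part within 1000 bp of any protein-coding start. Distal peaks were counted for a gene when they lay within 50 kb of its body. Shares carry 95% exact Clopper-Pearson intervals. Overlap meant at least 1 bp, and was compared with 100 circular shifts of a replicate along each chromosome. Places in the genome were compared with 100 random placements per peak on its chromosome. Correlations used signal in regions of the ranked list of both replicates that matched a region in each replicate's own ranked list, 34852 of 57908.

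The gene lists, motifs, tests, thresholds, loci and most alternatives were fixed before the data were examined. Of 410 entries in 20 lists, 409 matched a gene, 394 of them distinct, and Ahsp was not analysed here. The lists were hepatic transcription factors, hepatic secreted proteins, adult hepatocyte metabolism, coagulation factors, complement factors, lipoprotein handling, erythroid, heme and iron handling, stem and progenitor, megakaryocyte, macrophage and granulocyte, lymphoid, endothelial, mesenchyme and mesothelium, cholangiocyte, other endoderm, neuronal, muscle, germ cell and housekeeping genes. Each list was compared with 10000 random lists of as many protein-coding genes, matched in 5 bins on promoter GC content for promoters and on the number of genes within 50 kb for distal peaks. Two-sided permutation p-values, of which 0.0002 is the smallest possible, were adjusted by Benjamini-Hochberg over the 20 lists. A list stood apart when the adjusted p was under 0.05 in both replicates.

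Motifs were searched as exact consensus matches on either strand within 100 bp on each side of the summit, for 26 motifs. Control windows lay 2 to 20 kb from a summit and outside peaks, weighted to the same GC content in bins of 2 percentage points. A motif was called when the ratio of shares was at least 1.5 (or as far below 1) and its 95% interval excluded 1 in both replicates. Differences between replicates were medians over a list's genes of the difference in percentile rank of signal, replicate 1 minus replicate 2, against 10000 random gene sets. This comparison, the correlation and the comparison of promoter with distal peaks were first computed with −log10 p-values by mistake, and the rank comparison also with promoter peaks of neighbouring genes, then computed as planned with signal, and the first versions were kept as alternatives.

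Named genes were chosen by rule. For each list these were the 3 members with the strongest promoter peak in the conservative list, the member with the most distal peaks, and up to 4 members, in list order, without a promoter peak in either replicate. The 10 strongest peaks and, for each replicate, the 5 genes with the strongest promoter peak absent from every list of the other were also named. Sequence matches of strong peaks were found with BLAST+ 2.17.0, at 50 bp or more and 90% identity or more for the mitochondrial genome, and at 80% or more of the length and 95% identity or more for other nuclear copies. Alternatives covered the peak list, the IDR threshold, the overlap rule, promoter width, window sizes, the random lists, motif controls, and leaving out each replicate. No paired analysis was possible because the replicates are 2 pools of 1 group.

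Calculations used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, numba 0.67.0 and matplotlib 3.10.9, with 11 as the random seed. The methods were tested on simulated data. Among 400 simulated lists without excess, the promoter test gave p under 0.05 in 4.25% with matched and 14.75% with unmatched random lists, the distal test in 7% and the rank test in 5.5%. When 50% of members were replaced by genes with a promoter peak, the promoter test found 39.5% of lists of 20 genes, and the rank test found 82% of lists shifted by 6 points. All these shares count p under 0.05 before adjustment over the lists. The rank test was run on invented normal values, so its share found does not measure its power on the real ranks after adjustment. A motif planted in 30% of windows gave a ratio of 7.44 where 7.37 was planted.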

Results

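Accessible chromatin was mapped by ATAC-seq, in which a transposase inserts sequencing adapters into open DNA, in livers of B6NCrl mouse embryos at embryonic day 11.5. At that age the liver holds hepatoblasts, the precursors of hepatocytes and bile duct cells, and is taking over blood formation. The 2 biological replicates formed 1 group of mixed sex. Replicate 1 was a pool of 162 embryos, and the labels give no number for the pool of replicate 2. With no second tissue, age or treatment, comparisons were drawn between the replicates, between gene lists and random genes, and between peaks and nearby DNA. The number of reads per library is unknown. All p-values describe these 2 libraries and measure spread among genes or random draws, not among animals, and intervals cover counting error only.

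Replicates 1 and 2 held 22069 and 21503 accessible regions past the authors' reproducibility threshold for each library, covering 16.4 Mb and 16.7 Mb. Of the regions of replicate 1, 85.4% (95% exact Clopper-Pearson interval 84.9 to 85.8) overlapped a region of replicate 2. In the other direction the share was 86.6% (86.2 to 87.1). Regions without a partner were weaker, with a median signal of 6.18 against 9.55 in replicate 1 and of 5.06 against 9.59 in replicate 2. After shifting the regions along each chromosome 100 times, the mean overlap was 1.28% and 1.32% and the highest 1.53% and 1.55%. Signal in 34852 matched regions correlated with a Spearman's rho of 0.886 and a Pearson's r of 0.889 on the log2 scale, across regions, which are not independent replicates. In 98.5% of these regions the replicates differed less than 2-fold. The number of regions rose to 47983 and 45832 in the overlap-thresholded lists, and to 46497 and 47441 when every summit was counted.

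Some promoters were accessible in 1 replicate with no overlapping peak in any list of the other. Replicate 1 had 412 such regions, 57 of them at promoters, and replicate 2 had 266, with 52 at promoters. The strongest in replicate 1 lay at Asb4, a substrate adaptor of ubiquitin ligases (signal 6.96), Wwc1, a regulator of Hippo signalling (6.86), and Ptgfr, the receptor of prostaglandin F (6.41). Cfap52 and Cachd1 followed with 5.92 and 5.82. In replicate 2 they lay at Smpd4, a sphingomyelin phosphodiesterase (5.92), Mex3d, an RNA-binding protein (5.71), Nup62cl (5.18), Wdr54 (4.99) and Gimd1 (4.93). All 10 signals were below the median of their replicate, 8.86 or 8.76. The difference between replicates was not tested at these promoters.

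Promoters of protein-coding genes held the largest share of regions past the threshold, 47.8% ± 0.88 (SD, n = 2). Introns held 27.4% ± 0.74, the space between genes 22.6% ± 0.14 and exons 2.19% ± 0.0051 (SD, n = 2 each). The promoter share was 21.4 and 21.9 times that of randomly placed regions in replicates 1 and 2, while introns held 0.746 and 0.717 times and intergenic DNA 0.393 and 0.390 times the random share. Promoter regions were also the strongest, with a median signal of 10.0 and 10.8 against 7.83 and 7.22 in introns. A promoter peak was present at 10787 and 10885 of 21827 protein-coding genes, 49.4% and 49.9%. A promoter was counted as accessible when it had a peak past the threshold of a replicate's list, so weaker peaks were not counted. In the overlap-thresholded lists the promoter share was 30.1%, below introns (35.8%) and intergenic DNA (30.8%).

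The X chromosome carried fewer accessible regions than the autosomes, 3.42 and 3.14 per Mb against 8.72 and 8.51. The ratio of X to autosomes was 0.381 ± 0.016 (SD, n = 2). The X chromosome also carried fewer protein-coding genes, 5.54 per Mb against 8.40. Chromosome 11, with 13.4 genes per Mb, had the highest density of regions with 13.6 and 13.5 regions per Mb, followed by chromosome 19 with 11.9 and 11.6. Chromosome 14 was the lowest autosome with 6.24 and 5.88. The Y chromosome held 9 and 15 regions. These values carry no test.

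Erythroid genes were accessible almost throughout. Of 33 erythroid genes, which encode globins, red cell membrane proteins and their transcription factors, 29 and 30 had a promoter peak in replicates 1 and 2, 1.94 and 1.99 times the share in random genes of like promoter GC content. Among them, Trim10, a tripartite-motif protein of terminal red cell differentiation, had the strongest promoter peak (signal 20.6 in both replicates together, 19.7 and 20.5 apart; mm10 chromosome 17, 36869265 to 36870118). Spta1, the spectrin of the red cell skeleton, had a signal of 17.1 (chromosome 1, 174171573 to 174172251), and Epb42, which ties that skeleton to the membrane, 16.8 (chromosome 2, 121036501 to 121037437). Gfi1b, a repressor in erythroid and megakaryocytic cells, and the embryonic globin genes Hbb-y and Hbb-bh1 had no thresholded promoter peak in either replicate, but the globin genes had one in both overlap-thresholded lists and Gfi1b in that of replicate 1. Heme synthesis and iron handling genes followed, with 19 of 20 accessible in each replicate (1.55 and 1.54 times random). Flvcr1, a heme exporter, had a promoter signal of 17.7, Cpox, an enzyme of heme synthesis, 15.1, and Slc25a37, the iron importer of mitochondria, 13.9, while Hfe, an upstream regulator of hepcidin, had no promoter peak in any of these lists. Housekeeping promoters were accessible at 23 and 22 of 23 genes (1.46 and 1.38 times), among them B2m (14.5), Pgk1 (13.7) and Sdha (13.7). Two-sided permutation p-values against 10000 random lists, adjusted by Benjamini-Hochberg over 20 lists per replicate, were 0.0008 and 0.00067 for the erythroid list, 0.00267 in both replicates for heme and iron handling, and 0.00114 and 0.0076 for housekeeping genes. With the overlap-thresholded lists, heme and iron handling (ratio 1.29, adjusted permutation p = 0.059) and housekeeping genes (1.23, 0.0507) no longer stood apart, and the housekeeping list also missed with the 20000 strongest peaks (1.36, 0.074).

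Stem and progenitor genes and megakaryocyte genes did not stand apart at promoters. Of 22 stem and progenitor genes, 12 and 14 had a promoter peak (0.935 and 1.08 times random, adjusted permutation p = 0.879 and 0.798). Hlf, a transcription factor of blood stem cells, had a promoter signal of 11.5, Ikzf1, a factor of lymphoid and progenitor cells, 11.3, and Runx1, which is needed for the emergence of blood stem cells, 10.4. Cd34, Erg, Fli1 and Hoxa9 were among the 8 without a thresholded peak in either replicate, of which Cd34 (5.35) and Fli1 (3.46) had one in the conservative list and Cd34, Erg and Fli1 in both overlap-thresholded lists. Of 16 megakaryocyte genes, 6 and 9 had one (0.880 and 1.31 times, adjusted permutation p = 0.879 and 0.364), with Gp1ba, a platelet receptor subunit, the strongest (10.9), then Nbeal2, needed for platelet granules (8.88), and Rab27b (6.21). The platelet genes Pf4, Ppbp, Gp1bb and Gp9 had no thresholded peak in either replicate, though Pf4 had one in the conservative list (3.87) and in both overlap-thresholded lists.

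Of 6 lists of hepatocyte genes, adult hepatocyte metabolism fell below random genes in both replicates, and 3 others did so only under other choices. Of 26 genes of adult hepatocyte metabolism, only 2 had a promoter peak in each replicate, 0.211 and 0.208 times the random share (adjusted permutation p = 0.0015 and 0.00267): Glul, glutamine synthetase (signal 13.7), and Ass1, a urea cycle enzyme (7.01). Hmgcs2, an enzyme of ketone body synthesis, had one in the conservative list (5.43) and in both overlap-thresholded lists. Among the 24 without a thresholded peak in either replicate were Cyp7a1 and Cyp8b1, enzymes of bile acid synthesis, and Cyp2e1 and Cyp1a2, which oxidise drugs. Of 25 hepatic secreted proteins, 4 and 3 had a promoter peak (0.468 and 0.348 times). Vtn, vitronectin, was the strongest (11.6), followed by Apob, the structural protein of lipoprotein particles (7.35), and Trf, the iron carrier transferrin (4.99), and the promoters of Alb, Afp, Ttr and Apoa1 had no peak past the reproducibility threshold in either replicate. Ttr had one in the conservative list of both replicates (4.76), Ttr and Apoa1 had one in both overlap-thresholded lists and Alb and Afp in that of replicate 2, and of the 20 genes without a thresholded peak 7 also had none in the overlap-thresholded lists. Hepatic transcription factors were accessible at 11 and 12 of 22 genes (0.735 and 0.795 times, adjusted permutation p = 0.14 and 0.244), among them Xbp1, a regulator of the secretory pathway (14.2), Foxa3, a forkhead factor (10.6), and Ppara, a regulator of fatty acid oxidation (9.91), while Hnf1a, Hnf1b, Foxa1 and Onecut1 had no thresholded peak in either replicate. Foxa1 (3.79) and Onecut1 (4.02) had one in the conservative list and in both overlap-thresholded lists, and Hnf1a and Hnf1b in the overlap-thresholded list of replicate 2. Lipoprotein handling genes had promoter peaks at 7 and 5 of 16 (0.797 and 0.562 times), with Mttp, which loads lipid onto Apob, at 12.2, Ldlr, the LDL receptor, at 9.60 and Scarb1, an HDL receptor, at 9.27. Of 18 coagulation factors, 3 were accessible in each replicate, Pros1 (10.3), F10 (7.37) and Plg (5.02), and of 14 complement factors 2 and 1, C8g (6.74) in both and Serping1 (6.24) in replicate 1. The secreted list passed the threshold in replicate 2 alone (adjusted permutation p = 0.0551 and 0.0123), and the coagulation, complement and lipoprotein lists in neither (lowest 0.0852). The secreted list passed in both with promoters of 500 bp (0.238 times) or unmatched random genes (0.282 times), and with the latter also the coagulation (0.337) and complement (0.216) lists. With the overlap-thresholded lists the adult hepatocyte list no longer stood apart (ratio 0.626, adjusted permutation p = 0.146).

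Most genes of other cell types lacked a promoter peak past the reproducibility threshold, and 9 such lists fell below random genes in both replicates. Some of these promoters had a peak in the overlap-thresholded lists, as did 8 of the 16 endothelial genes with no thresholded peak in either replicate. None of 19 skeletal and cardiac muscle genes had a thresholded promoter peak in either replicate, and 4 had one in an overlap-thresholded list. In the conservative list of both replicates, muscle genes with a promoter peak had a median signal of 4.07. Macrophage and granulocyte genes had 1 of 23 in each (Spi1, the factor PU.1, signal 5.39), germ cell genes 1 and 2 of 18 (Dazl, an RNA-binding protein, 11.8, and Stra8, which responds to retinoic acid, 5.90), and other endoderm genes 2 of 17 (Nkx6-1, a pancreatic factor, 13.5, and Lgr5, a Wnt pathway receptor, 4.61). Lymphoid genes had 2 of 18 in each replicate, Ebf1, a B cell factor (14.5), and the kinase gene Lck (6.98). Endothelial genes had 4 and 2 of 20, with Egfl7 (4.90) accessible in both and Pecam1, Cdh5, Kdr and Flt1 in neither, although Kdr and Flt1 had a peak in both overlap-thresholded lists and Kdr one in the conservative list (5.48). Mesenchyme and mesothelium genes had 3 and 2 of 24, among them Pdgfra, a growth factor receptor (7.59), and Lhx2, a factor of stellate cells (6.66), but not the collagen genes Col1a1, Col1a2 and Col3a1, of which the first 2 had one in both overlap-thresholded lists. Cholangiocyte genes had 3 of 12, the Notch receptor Notch2 (9.26), its ligand Jag1 (7.91) and Sox4 (5.09), but not Krt7, Krt19, Sox9 or Epcam, the last 2 of which had one in both overlap-thresholded lists. Neuronal genes had 6 and 7 of 23, with Map2 (11.3), Syp (9.82) and Elavl4 (8.17) strongest. Ratios to random ranged from 0 for muscle to 0.527 for neuronal genes in replicate 2, and the highest adjusted permutation p was 0.0188. With the overlap-thresholded lists the lymphoid, endothelial, mesenchyme, cholangiocyte and neuronal lists no longer stood apart. The lymphoid list also missed with the conservative list of both replicates, the cholangiocyte list with unmatched random genes, and the neuronal list with those or promoters of 2000 bp on each side.

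Accessible regions away from promoters gathered around erythroid and stem and progenitor genes. Erythroid genes had a mean of 4.03 and 4.06 distal peaks within 50 kb in replicates 1 and 2, against 1.23 in random lists of like gene density (3.28 and 3.30 times). Globin genes of a cluster share peaks, which were counted for each of them, so these means and ratios hold repeated peaks. The list still stood apart with 1 member per group of neighbours, and against random lists matched on gene length and density. Sox6, a factor that silences embryonic globin, had the most, 13 in the conservative list of both replicates, and Hbb-y and Hbb-bh1, without a thresholded promoter peak, had 11 each in overlapping windows. Stem and progenitor genes had 2.73 and 2.82 (2.64 and 2.85 times), led by Ikzf1 with 11. Heme and iron genes had 2.20 and 2.40 (1.78 and 1.93 times), Fech, which inserts iron into heme, the most with 8, without passing the threshold. Lipc, hepatic lipase, had 10, Hpd, an enzyme of tyrosine breakdown, 8, Rab27b and Actb 7, and Serpinf2, Notch2, Cx3cr1 and Eng 6 each, although none of their lists stood apart. Tnni3, Vil1, Ddx4 and Rxra had 5 each, and F5, C3, Cd79a, Col1a1, Elavl4 and Gad2 had 4. Adjusted permutation p-values were 0.004 and 0.006 for each of the erythroid and progenitor lists and 0.0853 or more for the other 18, of which none fell below random genes. The erythroid excess was 2.43 times with the overlap-thresholded lists, where its adjusted permutation p was 0.052.

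**Figure D1:**
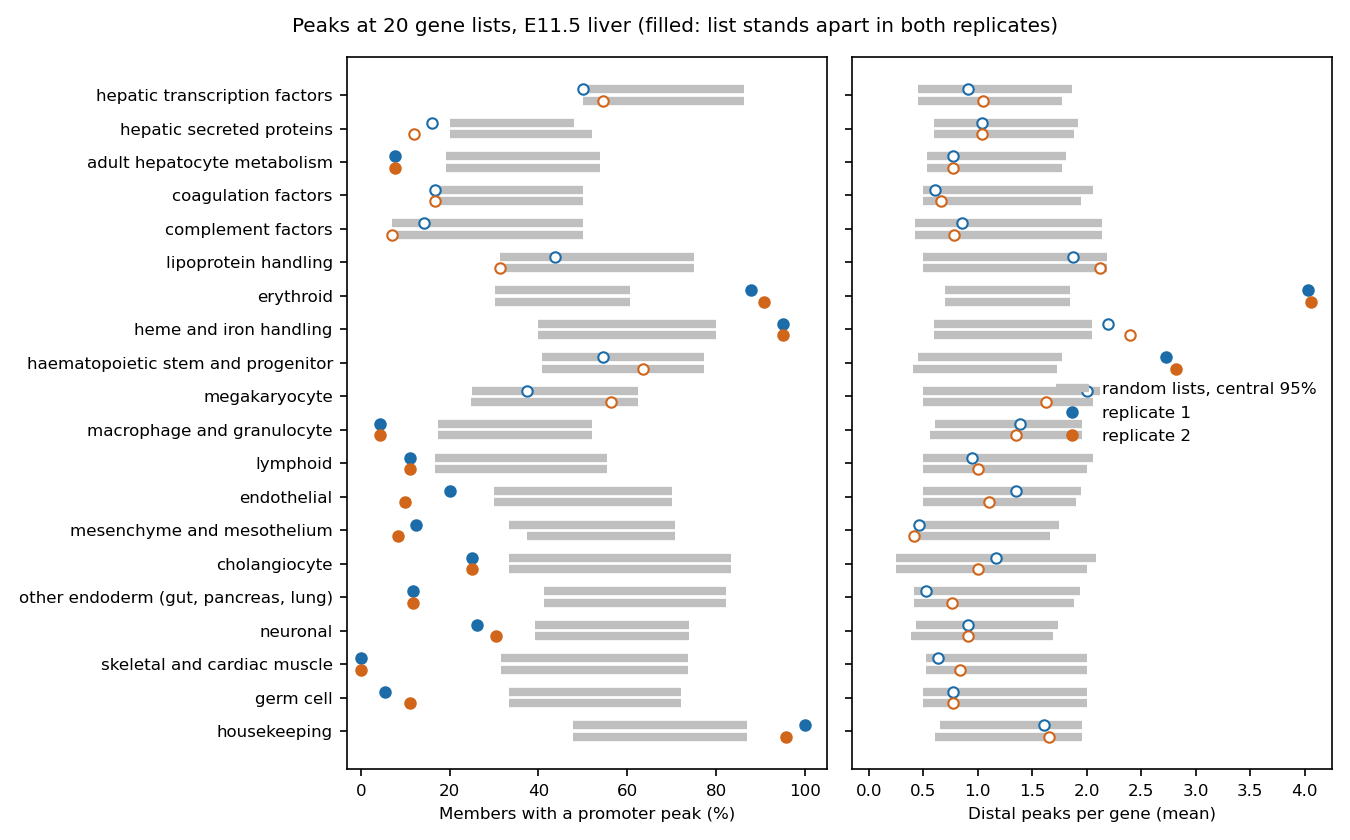
Share of genes with a promoter peak in percent (left) and mean number of distal peaks per gene (right) for 20 gene lists, where points are the 2 replicates, grey bars the central 95% of random lists and filled points mark lists that stood apart in both replicates. Erythroid genes lay above the random range on both sides (29 and 30 of 33 promoters, 4.03 and 4.06 distal peaks), and muscle genes had 0 of 19 promoters.

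The globin clusters were densely accessible and the albumin and alpha-fetoprotein genes almost without peaks. Around Hbb-bt, an adult beta globin gene (chromosome 7, 103762524 to 103863996), the conservative list of both replicates held 13 regions, with 11 past the threshold in each replicate. Among the 13 were regions nearest to the olfactory receptor genes Olfr68 (signal 14.1, the strongest in the window), Olfr67 (12.9) and Olfr69 (10.2). The strongest at a globin promoter there lay at Hbb-bs (103827332 to 103828214, signal 10.2), and Hbb-bt had one of 6.71 (103813567 to 103814153). Upstream of Hbb-y, on the side of the locus control region, lay intergenic regions at 103859141 to 103859496 (12.4) and 103860928 to 103861286 (9.21). Around Hba-a1 (chromosome 11, 32233511 to 32334465) 12 regions were found, 10 and 11 in the replicates. The strongest were in introns of Nprl3, the neighbouring gene that houses alpha globin enhancers, at 32255989 to 32256849 (18.0), 32250727 to 32251360 (15.2) and 32245364 to 32246046 (14.1). The windows of Alb and Afp, the main plasma proteins of the adult and fetal liver, shared a single intergenic region (chromosome 5, 90509780 to 90510730, signal 3.55), and neither replicate's own thresholded list had one. The overlap-thresholded lists added weak regions, 5 and 12 around Alb in replicates 1 and 2 and 5 and 10 around Afp. Gata1, the main erythroid factor (chromosome X, 7909260 to 8028071), had 4 regions in each replicate, including its promoter (7967761 to 7968838, 7.93) and an intron (7971315 to 7971785, 8.30). Hnf4a, a main hepatocyte factor (chromosome 2, 163456808 to 163622910), had 7 in the conservative list and 3 in each replicate, and the 4 inside the gene had signals of 3.58 to 5.24. Those of each replicate included the promoters of the neighbours Fitm2 (10.4) and Ttpal (10.4). The thresholded region inside Hnf4a differed between the replicates. The number of distal peaks put Hbb-bt at the 98.6 percentile of protein-coding genes, Hba-a1 at 97.5, Hnf4a at 83.5, Gata1 at 60.6 and Alb at 40.5. The overlap-thresholded lists raised the counts to 19 and 20 at Hba-a1, 8 and 7 at Gata1, 9 and 12 at Hnf4a and 16 and 17 at Hbb-bt.

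**Figure D2:**
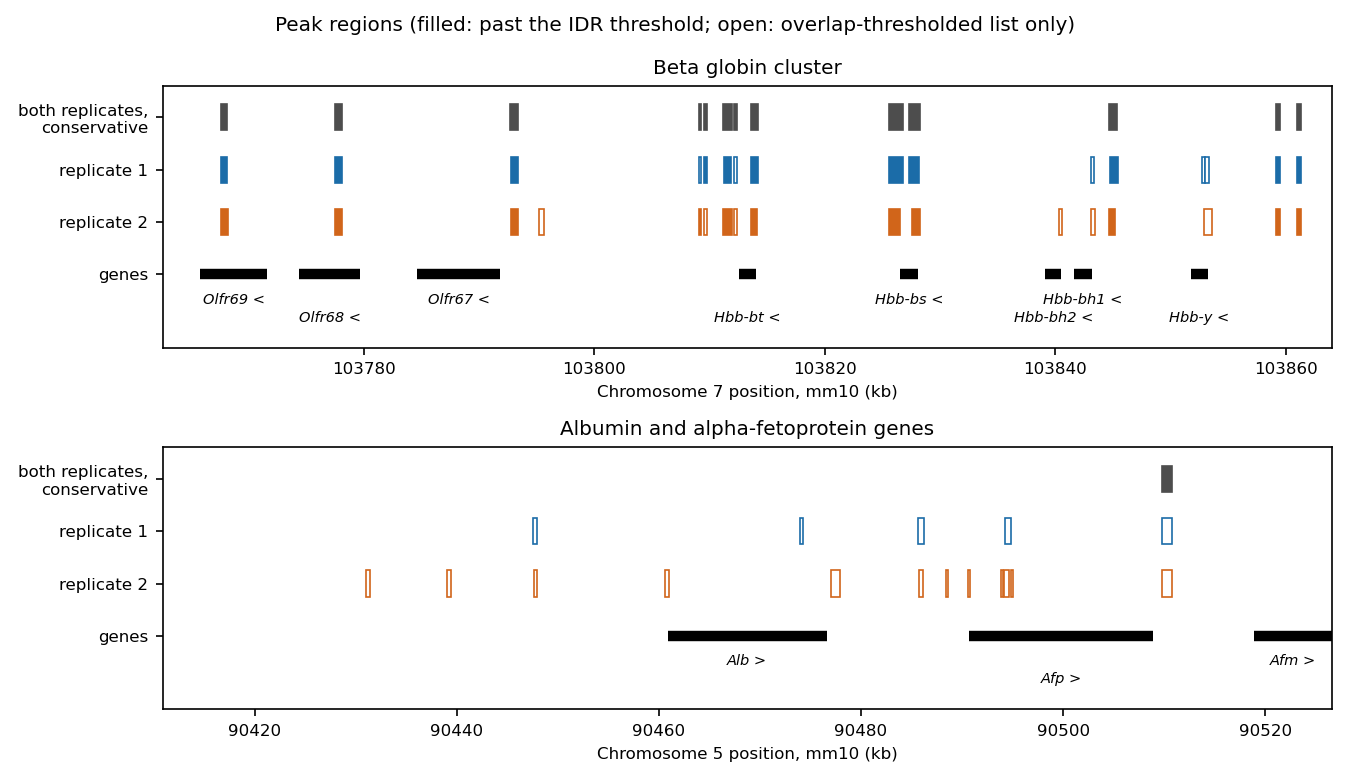
Accessible regions at the beta globin cluster on chromosome 7 and at Alb and Afp on chromosome 5, drawn by mm10 position, with filled boxes for regions past the reproducibility threshold and open boxes for regions in the overlap-thresholded list alone. The beta globin window holds 11 filled regions in each replicate and the Alb window none.

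Distal regions were rich in GATA and GATA composite motifs, and 15 of 26 motifs were enriched in both replicates. The GATA motif occurred in 31.6% and 30.9% of distal summit windows of replicates 1 and 2. That was 10.6 (95% counting interval 10.16 to 11.001) and 10.7 (10.3 to 11.2) times the share in GC-matched windows outside peaks. The sequence does not tell which GATA factor binds, Gata1 of the erythroid, Gata2 of the progenitor or Gata4 and Gata6 of the hepatic list. The composite of an E-box and a GATA site, where Tal1 binds with Gata1, occurred in 19.7% and 19.9%, 26.7 (24.9 to 28.7) and 27.4 (25.4 to 29.5) times control. CTCF, which marks chromatin loop anchors, was enriched 17.9 and 14.9 times, NF-E2, a factor of globin enhancers, 7.45 and 7.86, and KLF, the family of the erythroid factor Klf1, 1.94 and 2.08. RUNX (2.11 and 2.32), MEF2 (2.28 and 2.38), SP1 (5.97 and 5.61), NRF1 (5.59 and 10.6), YY1 (7.83 and 6.49), ETS (2.88 and 2.69), AP-1 (1.95 and 1.91), NFY (1.86 and 2.00), C/EBP (1.58 and 1.95) and HNF1 (10.1 and 19.4, from 6 and 5 windows) made up the rest. Of these, C/EBP and HNF1 are motifs of factors on the hepatic list. NR5A2, a nuclear receptor of liver and pancreas, was depleted (0.440 and 0.433 times). Motifs of the other hepatic factors, HNF4A (1.01 and 1.15), FOXA (1.27 and 1.36) and ONECUT (0.851 and 0.878), were not called. The FOXA intervals (1.16 to 1.40 and 1.24 to 1.49) lay above 1, but its ratios were under 1.5. PU.1, TEAD, MYOD E-box, CRX and REST were not called either, and GRHL (2.21 times) and SOX (0.542 times) passed in replicate 2 alone. Near erythroid genes 38.5% and 39.4% of distal windows held the GATA motif, and the intervals (28.8 to 49.0 and 29.7 to 49.7) included the share in all distal windows. Other controls turned the direction of ETS (0.975 times), NR5A2 (1.17 times) and C/EBP (0.836 times), and AP-1, RUNX, NFY, YY1, HNF1, C/EBP and NR5A2 each lost the call in 1 or more alternatives. Motifs not called above passed in some alternatives, HNF4A in 2 (1.80 and 1.90 times), PU.1 in 3 (1.52 to 1.84 times) and FOXA in 1 (1.78 times). ONECUT (0.118), CRX (0.545), MYOD E-box (41.4), TEAD (1.78) and GRHL (0.226) changed against reversed sequences, REST (3.31) in the overlap-thresholded lists, and GRHL (1.71) and SOX (0.551) with other window lengths. A reversed motif keeps its bases but not its dinucleotides. The MYOD E-box gains a CpG (a C followed by a G), and ONECUT, GRHL and ETS lose theirs. Changes against reversed sequences can therefore come from CpG content alone and do not bear on the calls.

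Promoter regions were rich in sites of broadly acting factors, with 13 motifs enriched in both replicates. ETS, the site of a factor family common at housekeeping promoters, occurred in 8.54% and 8.85% of windows (22.1 and 13.98 times control), and NFY, which binds CCAAT boxes, in 20.4% and 20.7% (8.89 and 11.4 times). YY1, a ubiquitous zinc-finger factor, occurred in 1.56% and 1.79%, 248 (49.6 to 1235) and 346 (159 to 750) times a rare control share. NRF1, a regulator of mitochondrial genes, was enriched 13.7 and 7.52 times, SP1 4.84 and 6.99, CTCF 6.71 and 3.51, the GATA composite 7.38 and 4.99 and GATA 3.18 and 2.67, which occurred in only 2.96% and 2.65% of promoter windows. FOXA (2.53 and 2.68), PU.1 (1.99 and 2.35), KLF (1.68 and 2.07), GRHL (4.67 and 2.70) and HNF4A (1.65 and 1.75) were also called, and the MYOD E-box was depleted (0.624 and 0.583). C/EBP (4.30 times), ONECUT (5.70 times) and HNF1 (34.96 times, from 1 window) passed in replicate 2 alone and REST (67.6 times) and TEAD (0.624 times) in replicate 1 alone, and NF-E2, AP-1, RUNX, NR5A2, MEF2, CRX and SOX were not called. No GC-matched control could be had for 1123 and 1126 of the promoter windows, which were left out. Controls were matched on GC content and not on dinucleotides. The size of the ratios of motifs that hold CpG, such as YY1, ETS, NRF1, SP1 and GRHL, may therefore partly reflect CpG content. Against shuffled windows that keep dinucleotides, 11 of the 13 calls were kept, and HNF4A and GRHL (0.845 times) lost theirs. HNF4A lost its call under each of the 6 other choices tried on both replicates, GATA, KLF and PU.1 under 1 each, and MYOD E-box and GRHL lost theirs or turned direction under 3 and 5. Calls were gained by C/EBP under 5 choices (2.53 to 4.02 times), ONECUT under 4 (3.09 to 5.00), REST under 2 (13.4 times or more), MEF2 under 2 (4.90 and 6.30) and RUNX under 1 (1.91). NF-E2 (10.1), ONECUT (0.513) and TEAD (1.69) turned direction against reversed sequences, which do not keep dinucleotides such as CpG.

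**Figure D3:**
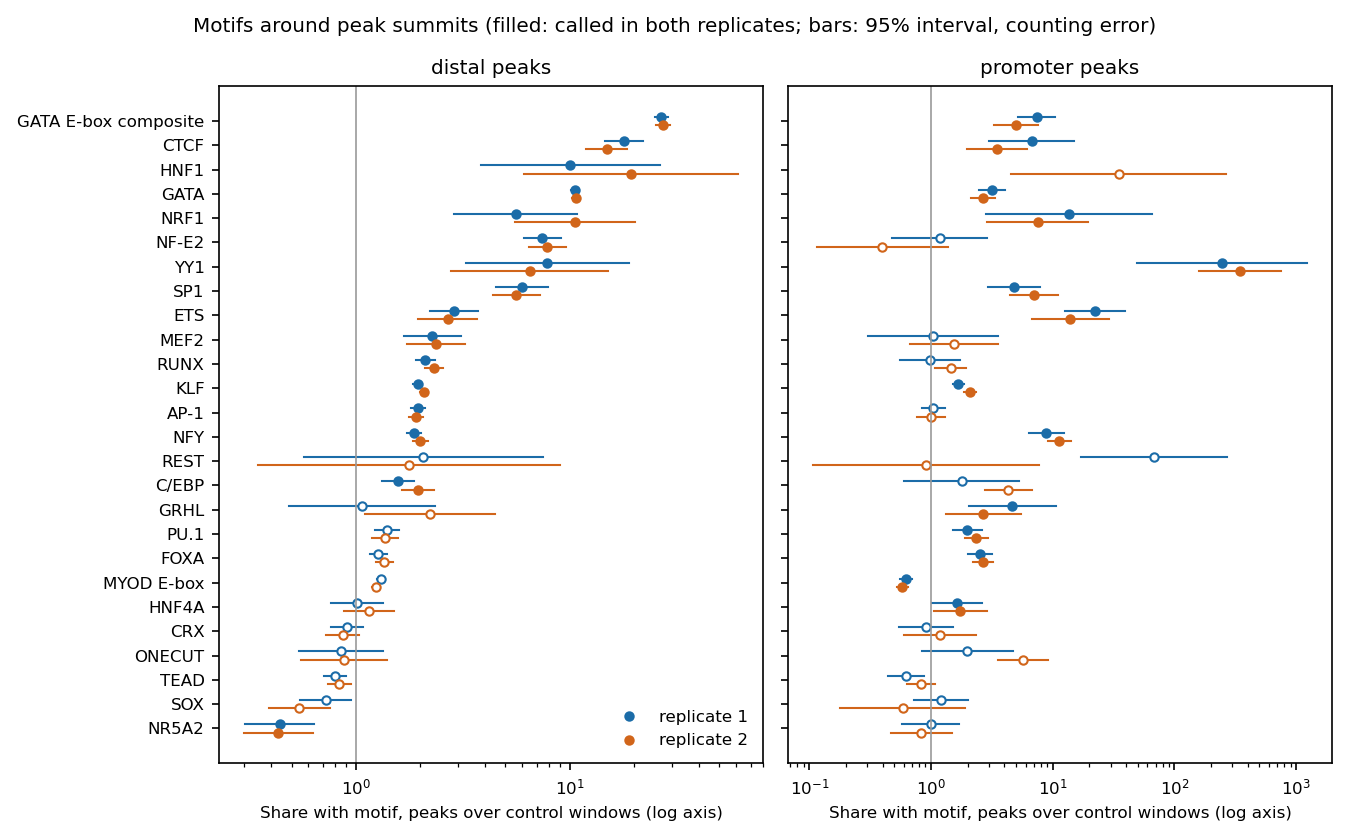
Ratio of the share of summit windows with each of 26 motifs to that of GC-matched windows outside peaks, on a log axis, for distal and promoter peaks in both replicates, with 95% counting intervals and filled points for motifs called in both replicates. The GATA composite lies at 26.7 and 27.4 in distal peaks, and YY1 at 248 and 346 in promoter peaks.

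The 10 strongest regions of the conservative list all lay away from promoters. The highest signals, 58.8 and 56.1, fell at chromosome 2, 69355469 to 69355735, nearest to Abcb11, the bile salt export pump, and at chromosome X, 143482936 to 143483180, nearest to the kinase gene Pak3. The others, from 31.0 to 44.4, were nearest to G6pd2, Gm5426, Rtl10, Frmd4a, Myl12b, Hic2, Cdh20 and Tyrp1, all intergenic except the region nearest to Rtl10, which lay in an intron of Gnb1l. Of the 10, 4 matched the mitochondrial genome in sequence, those nearest to Abcb11, G6pd2, Gm5426 and Tyrp1, against 0 of 200 other distal peaks (two-sided Fisher's exact p = 2.67e-06). The conservative list lacked 79 chromosomal regions that passed its threshold in the ranked list of both replicates, 14 of them with another nuclear copy. Of these 79, at least 3 had signals above the lowest of the 10 (43.0, 33.2 and 31.2), and 1 matched the mitochondrial genome (chromosome 1, 24611582 to 24616161). Why they are absent was not tested, and the number of reads behind these signals is unknown.

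No gene list passed the test for a difference in rank between the replicates. Peaks near 14 other endoderm genes ranked a median of 7.0 percentile points higher in replicate 1, with 11 of the 14 genes higher there. The mesenchyme list was 5.86 and the lymphoid list 5.83 points higher in replicate 1. The lipoprotein list stood at -4.58, the heme and iron list at -3.82 with 2 of 20 genes higher in replicate 1, the hepatic transcription factors at -3.66 and the erythroid list at -1.55. Over all matched regions the median difference was -2.17 at promoters and 1.00 in distal regions. The random gene sets were not matched on the share of promoter peaks, so a list's value may partly reflect that share, which was not tested. By two-sided permutation of genes, 0 of 20 lists passed after adjustment (lowest adjusted p = 0.148) and 4 had an unadjusted p under 0.05. With −log10 p in place of signal 3 lists passed, hepatic transcription factors, lipoprotein handling and muscle, all higher in replicate 2, with distal peaks alone 1, lipoprotein handling, and with peaks past the reproducibility threshold 2, other endoderm and mesenchyme.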

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

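Of the tests below, the one that joined GC content and peak strength was chosen only after the result was seen. The versions with −log10 p-values were unplanned. They were computed first, by mistake, and kept after the planned versions with signal were run.

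The ranked list of both replicates held 264 records past the conservative list's threshold that the conservative list lacks. They made up 264 of 62105 such records, 91 on scaffolds outside the assembled chromosomes and 173 on chromosomes in 79 regions, with a median −log10 p of 160.5 against 86.9 in the conservative list. The conservative list held no region on a scaffold at all. Of the 79 regions, 14 had another nuclear copy and 1 matched the mitochondrial genome. Whether the absent records mark accessible chromatin was not tested.

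Distal peaks were rich in the composite of an E-box and a GATA site, while the HNF4A motif of hepatocytes was not enriched. A mixture of blood and hepatic cells with separate distal elements is a candidate explanation, under which peaks with the composite would hold HNF4A sites less often than peaks without it. The ratio of HNF4A shares was 0.916 (95% interval 0.458 to 1.83) in replicate 1 and 0.925 (0.474 to 1.81) in replicate 2. Only 10 and 11 windows held both motifs, and HNF4A occurred near its control share in distal peaks (1.01 and 1.15 times). Matches at the background rate would give a ratio near 1 with or without a mixture, so the ratio cannot tell a mixture from shared elements. HNF4A was called in the overlap-thresholded lists (1.80 times), where this test was not run. Apart from this mixture no biological explanation was tested, since the design has 1 group.

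The strongest peaks lay away from promoters. Reads shared with mitochondrial DNA could raise such peaks, and 4 of the 10 strongest matched the mitochondrial genome, against 3 of the next 100 and 0 of 200 other distal peaks. Reads shared between nuclear copies could too, and 2 of the 10, both also among the mitochondrial matches, had another copy on the chromosomes. Both counts fell between the bounds set for and against, so mitochondrial reads stay open for the 4 regions and nuclear copies for 2 of them, and the other 6 matched neither. No biological explanation was tested.

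Promoter peaks were relatively stronger in replicate 2, by a promoter minus distal difference of 0.20 (95% bootstrap interval 0.191 to 0.207) in the median log2 ratio of signal and 0.37 (0.356 to 0.385) in that of −log10 p. Within bins of GC content the difference was 0.151 (0.138 to 0.165) and 0.239 (0.215 to 0.259), and within bins of peak strength 0.132 (0.123 to 0.142) and 0.213 (0.195 to 0.228), more than 50% of the full difference in each case, which argues against either as the whole cause. Within joint bins of both it was 0.0779 (0.0638 to 0.0913) and 0.0749 (0.0520 to 0.101), so GC content and strength together cannot be told apart from another cause that remains, because the share left, 39.2% and 20.2%, lies between or across the bounds. No biological explanation was tested, and the number of embryos in replicate 2 is not stated.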

How the results depend on the processing

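Of the alternatives below, counting every summit and correlating promoter peaks alone were chosen only after the result was seen. So were keeping 1 member per group of neighbours and matching on gene length. Counting promoter peaks of neighbouring genes and using −log10 p were unplanned too. Both were computed first, by mistake, and kept as alternatives after the planned versions were run. For every change listed here the cause was not tested, except that longer lists and other definitions change counts and shares by construction.

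The overlap-thresholded lists gave 47983 and 45832 regions, overlaps of 75.3% and 77.1%, shares of 30.1% at promoters, 3.29% in exons, 35.8% in introns and 30.8% between genes, an X ratio of 0.325, 1 list above and 4 below random genes at promoters, and 1 list above in distal peaks. Counting every summit gave 46497 and 47441 records and shares of 61.0%, 1.86%, 19.5% and 17.7% in the same order. Overlap was 80.4% and 82.5% at 50% reciprocal overlap, 78.6% and 80.6% for summits within 100 bp, 98.1% and 98.7% against the other replicate's overlap-thresholded list, and 86.9% for the 20000 strongest peaks of replicate 1. Shares in that order were 44.7%, 2.51%, 29.1% and 23.7% with promoters of 500 bp, 50.8%, 1.91%, 25.5% and 21.8% with 2000 bp, 51.7%, 2.58%, 28.6% and 17.2% with all annotated genes, and 49.2%, 2.00%, 26.6% and 22.2% for the 20000 strongest peaks. The correlation was 0.895 past the IDR threshold, 0.831 in distal peaks, 0.901 in promoter peaks, 0.889 as Pearson's r and 0.918 with −log10 p. Lists called between replicates numbered 1 with distal peaks only, 2 past the IDR threshold and 3 with −log10 p.

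Against reversed sequences, motif ratios changed direction for ETS (0.975), NR5A2 (1.17), TEAD (1.78) and GRHL (0.226) in distal peaks and for NF-E2 (10.1), ONECUT (0.513), TEAD (1.69), MYOD E-box (7.61) and GRHL (0.232) in promoter peaks. Reversed motifs differ from the motifs in dinucleotides such as CpG, so these changes cannot be read for or against a call. Alternatives called 12 to 17 motifs enriched in distal and 12 to 16 in promoter peaks, from 15 and 13. They kept 11 to 15 of the 15 and 9 to 13 of the 13, fewest with 250 bp windows in distal peaks and against reversed sequences in promoter peaks. Against shuffled windows ratios changed direction for C/EBP (0.836) in distal and GRHL (0.845) in promoter peaks.

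Among main results, 70 alternatives left a count within 1.5-fold, a share or ratio within 1 SD of the replicates, or an overlap or correlation within its 95% interval, and 49 moved it. Some of the 70 could not have moved. With 2 replicates, each share lies within 1 SD of the mean when a replicate is left out. No regions overlapped, so merging them could not change a count. Among single lists, motifs and loci, 813 kept their call or, for loci, a like count, 43 newly passed and 42 no longer passed. Another 11 reversed direction with a call in either version, and 11 locus counts moved. Where neither version was called, direction was not compared, so changes of direction there are among the 813. Most losses at promoters (8 of 13) came with the overlap-thresholded lists. Without replicate 1 the hepatic secreted list passed (0.348), and without replicate 2 no list changed its call. Calls needed both replicates, so leaving out a replicate could add a list or motif call but not remove one. Some of the 813 were therefore fixed in advance. Promoters of 500 bp (0.238) and unmatched random genes (0.282) also brought that list past the threshold, and unmatched genes the coagulation (0.337) and complement (0.216) lists. Without replicate 1 or 2 the promoter share ranged from 47.2% to 48.4%. Depth is unknown, so an absent peak cannot be read as closed chromatin.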

Other observations

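The gene families below, chosen by symbol only after the lists were seen, carry no test.

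Promoter peaks were present at most members of several gene families. A promoter peak was present in replicates 1 and 2 at 77 and 79 of 83 ribosomal protein genes (92.8% and 95.2%), 36 and 36 of 39 proteasome genes, 45 and 46 of 46 NADH dehydrogenase subunit genes, and all 6 genes of the replicative helicase family Mcm. Clustered histone genes, which supply chromatin in dividing cells, had 60 and 62 of 67, and Kruppel-like factors, which include the erythroid regulator Klf1, 15 and 14 of 17. RAB proteins of vesicle traffic had 52 and 55 of 69, zinc-finger genes named Zfp 277 and 285 of 365, and solute carriers 179 and 193 of 371, 48.2% and 52.0%, close to the 49.4% and 49.9% of all protein-coding genes.

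Other families mostly lacked one. Hox genes, which set position along the body axis, had 0 and 1 of 39 although their median promoter GC content, 56.8%, was close to the 57.4% of ribosomal protein genes. T-box genes had 2 and 3 of 13, keratins 1 and 0 of 53, and protocadherins 7 and 5 of 68. Cytochrome P450 genes of families 2 to 4, which oxidise drugs and fatty acids in adult liver, had 4 and 7 of 72 and serpins, many of them plasma proteins, 5 and 4 of 61. Olfactory receptor genes had 6 of 1091 in each replicate and vomeronasal receptor genes 1 of 330.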
